A study of Mus musculus with 43 samples.

How the data were processed

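Proximal tubules of female and male C57BL/6 mice aged 6 to 8 weeks were dissected by hand into their S1, S2 and S3 parts, with 2 to 5 tubules taken for each sample. The labels list 43 samples: 19 RNA-seq libraries, from female mice, and 24 ATAC-seq libraries of both sexes, 4 for each sex and segment. The RNA-seq libraries number 6 for S1, 6 for S2 and 7 for S3. The number in each title was read as the animal, although the labels do not say so. By that reading S1 came from 2 animals (numbers 4 and 5), S2 from 3 (1, 2 and 3) and S3 from 4 (2, 3, 4 and 5), so S1 and S2 shared no animal.

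Per the labels' protocols, RNA was turned into cDNA with a SMARTer V4 ultra-low-input kit using 10 to 12 PCR cycles, tagmented with Nextera XT, and sequenced as 50-base read pairs. The kit primes from poly(A) tails and the protocol names no molecular identifiers and no strand marking. PCR copies may therefore remain in the values, and reads from overlapping genes on opposite strands could be assigned to either. Per the submitters' processing notes, the mouse build was mm10, and the tools named for the series were cutadapt, STAR, RSEM, Bowtie2, Picard, SAMtools and MACS2. Which of these made the expression values, and with which gene annotation, is not given in the sources used here.

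The authors deposited gene expression as TPM, transcript abundance scaled to a fixed total, with 1 value per gene and segment. Each TPM column sums to close to its nominal total (999907 for S1, 999988 for S2 and 999911 for S3) and is rounded to 1 decimal. How the libraries of a segment were combined into 1 value is not given in the sources used here. The values are the authors' own, without an SD or n. TPM keeps no read depth, so the depth is unknown and no counting interval or detection floor was computed. The table has 8 value columns. The 3 that match the female RNA-seq groups were used. The other 5 match no labelled RNA-seq group and were not used in any step, so the sexes were not compared. The ATAC-seq samples were not analysed here.

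A limma test on means per animal, with the animal as a random block, had been fixed before the data were examined. It needs values per library and could not be run on 1 value per segment. The replicate-level alternatives (block terms, single libraries left out, moderation settings, gene set tests) fell away with it. In its place the segments were compared by size alone. There is no replicate check, no p-value is given, and each difference describes these 3 columns.

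Of 54532 genes in the table, 16053 had a TPM of at least 1 in at least 1 segment and were compared. Differences are on the log2(TPM + 1) scale, that is with a pseudocount of 1, which understates the fold of low genes. A gene was counted as higher or lower when this difference was at least 1, which is 2-fold. Plain TPM ratios are given where both values are at least 1. Genes named for a contrast are, in each direction, the 10 with the greatest difference among those with a TPM of at least 10 in the higher segment, passing over symbols of the forms Gm plus digits and Rik. The parts of that rule that needed replicates could not be applied. Members of the fixed gene lists are also named, whatever their difference. Some genes that this rule takes are not reported here.

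The 32 gene lists (21 of segment markers, transport, metabolism, regulation and stress, and 11 of markers of other cell types and sex-linked genes) were also fixed before the data were examined, from general knowledge. They hold 350 different genes, of which 30 are in more than 1 list. For each list with at least 3 measured members, the median difference was placed among the medians of 10000 random lists of the same size, drawn from other genes in the same 20 bins of mean expression. That percentile describes where the list stands in these columns and is not a test across animals. Over 25 such lists and 3 contrasts, 49 of 75 medians lay outside the 2.5th to 97.5th percentile.

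Simulated data tested the code on the 16053 genes compared. Each column was copied with noise and 200 genes of at least 10 TPM were changed. In each of the 3 simulations 100% of the genes changed 4-fold passed the 2-fold threshold on the right side, and 0% of those changed 1.3-fold did. The noise was small beside that threshold and was not taken from the spread between libraries, which is unknown. These shares check the code and are not error rates of the calls. Another 200 lists were drawn at random from all genes, without leaving out the changed ones. Of these, 6% lay outside the 2.5th to 97.5th percentile in the simulation from S1, 3% in that from S2 and 3.5% in that from S3.

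Symbols came from the table. 54409 of the gene IDs matched a reference table of names, which was used to restore 27 symbols that a spreadsheet had turned into dates. 203 IDs share a symbol with another, and for list members the one with the higher mean was taken. Coordinates are 1-based, from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is built on. 14210 of the compared genes had a match. An exact 0 in the table was not read as absence: mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, which every respiring cell uses, are listed at 0 in each segment. Members of close gene families (Cyp2a4, Akr1c18, Slc22a19, Serpina1f, Cyp2d9, Ugt2b38 and others) may share reads with near copies, and their values are uncertain to that extent.

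Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter of TPM 5, quantile normalization and median-of-ratios scaling (10797 genes with a TPM above 1 in each column). Removing mitochondrially encoded genes, Gpx3 and Kap before rescaling, and keeping protein-coding genes alone, were added after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.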

Results

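RNA-seq measured gene expression along the proximal tubule of the female mouse kidney, the first part of the nephron after the glomerulus, where most filtered glucose, amino acids, phosphate and bicarbonate are taken back. The tubule has 3 successive parts: S1, S2 and S3. The study asked how gene expression and chromatin differ along this tubule and between the sexes. Here the 3 female expression profiles were compared. They stand for 6 libraries of S1, 6 of S2 and 7 of S3, given as 1 TPM value per gene and segment. There is thus no replicate check on any difference below, and the depth behind the values is unknown. By the numbers in the titles, S1 and S2 came from different animals.

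Of the 16053 genes compared, 5338 (33.3%) differed at least 2-fold between their highest and lowest segment. The highest value was in S1 for 1669 of these, in S2 for 2040 and in S3 for 1629. Genes at least 2-fold above both other segments numbered 968 in S1, 838 in S2 and 321 in S3. The order of S1 and S2 depended on the processing: it turned with pseudocount 0.1 (1215 and 2063) and without mitochondrially encoded genes, Gpx3 and Kap (886 and 1060). Among such genes with a TPM of at least 100, the numbers were 218, 28 and 49, so most in each segment were below that level. With a filter of TPM 5 in at least 1 segment they were 741, 317 and 163. Conversely, of all genes compared, 1506 were at least 2-fold lower in S1 than in both others, 26 in S2 and 456 in S3. S1 detected 12174 genes at a TPM of at least 1, S2 15121 and S3 12873.

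The most abundant transcripts differed between segments. Gpx3, the secreted glutathione peroxidase that the proximal tubule releases to plasma, took 11.4% of the TPM total in S1, 1.27% in S2 and 0.349% in S3. Kap, the androgen-regulated kidney protein (chromosome 6, 133849855 to 133853667, GRCm38.p6), took 0.00565% in S1, 6.43% in S2 and 9.57% in S3. Mitochondrially encoded genes took 6.50%, 16% and 9.72%.

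The segment markers separated the profiles. The 9 measured S1 markers were at least 2-fold higher in S1 than in S2 and in S3. Slc5a2, the low-affinity sodium-glucose cotransporter SGLT2, was at 2808 TPM in S1, 1.3 in S2 and 0.5 in S3. The gene lies on chromosome 7 from 128265683 to 128272430 (GRCm38.p6). Slc5a12, a sodium-coupled lactate transporter, was at 376 TPM in S1, 0.4 in S2 and 0.1 in S3. Slc34a1, the main renal sodium-phosphate cotransporter, was at 10241, 2227 and 17 TPM, and Gatm, the first enzyme of creatine synthesis, at 4072, 187 and 1.0. The 11 S3 markers were at least 2-fold lower in S1 than in S3, and 9 of them at least 2-fold lower in S1 than in S2. Slc7a12, an amino acid transporter, was at 2.5 TPM in S1, 1613 in S2 and 3048 in S3. Slc5a1, the high-affinity glucose transporter SGLT1, was at 0.1, 58.5 and 66.7 TPM. Between S2 and S3 just 1 of the 11, Cyp7b1 (0.5 and 3.3 TPM), differed 2-fold. Of the 5 S2 markers, Slc22a6, the organic anion transporter OAT1, and Slc13a3, a dicarboxylate transporter, peaked in S2. Slc22a6 was at 6.0, 217 and 1.0 TPM and Slc13a3 at 2.2, 227 and 1.1. Slc22a8 was alike in S1 and S2 (297 and 349 TPM) and at 0.7 in S3, while Slc17a3 (621 and 878 TPM) and Slc22a30 (22.9 and 22.4) differed less than 2-fold between S2 and S3.

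**Figure D1:**
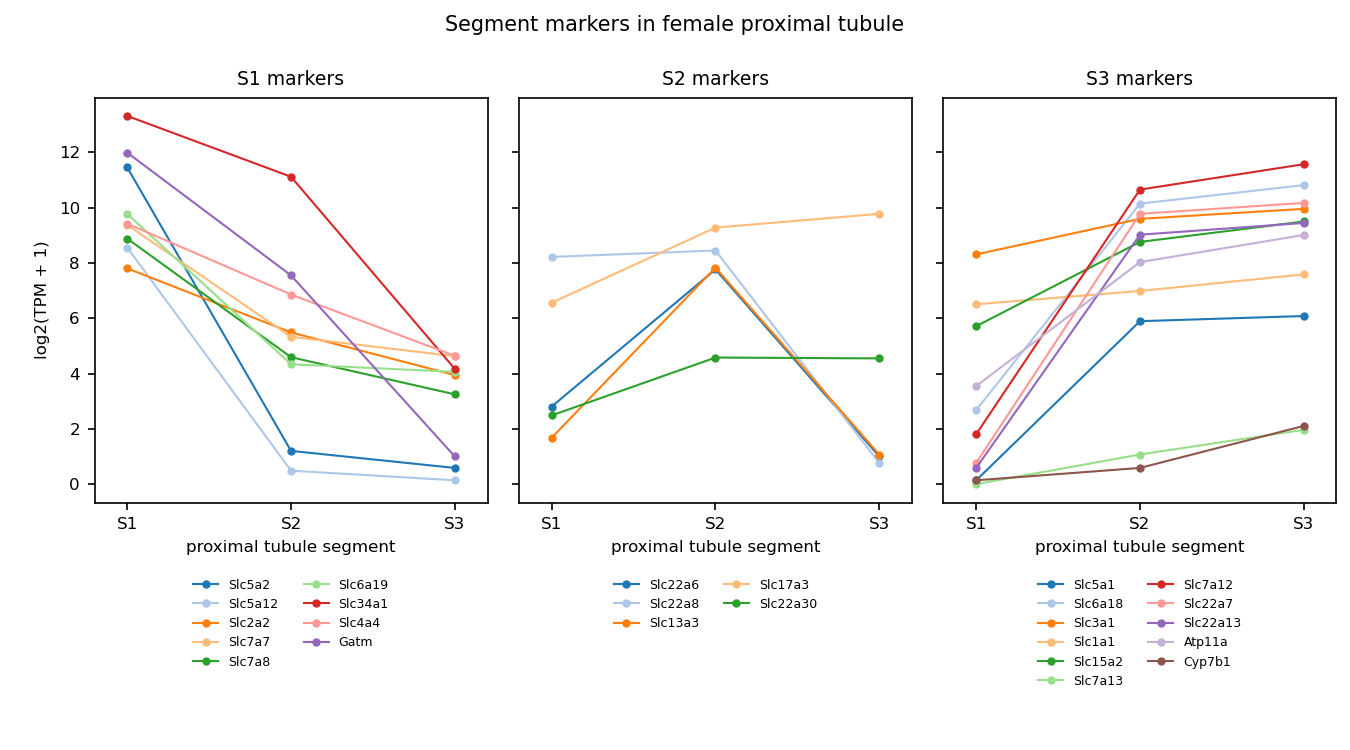
Expression of the S1, S2 and S3 marker lists in the 3 segments of the female proximal tubule. Each line is 1 gene, with log2(TPM + 1) on the y axis and the segment on the x axis, and each point is the authors' single value. Slc5a2 goes from 2808 TPM in S1 to 1.3 in S2, Slc22a6 and Slc13a3 peak in S2, and S3 markers such as Slc7a12 are already high in S2.

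S1 against S2 addressed how the first part of the tubule differs from the middle one. Besides the markers above, Slc34a3, a phosphate transporter, was 310-fold higher in S1 (404 against 1.3 TPM). Fabp3, a fatty acid-binding protein, was 72.7-fold higher (639 against 8.8 TPM), and Acss1, which makes acetyl-CoA from acetate in mitochondria, 57.8-fold (682 against 11.8 TPM). Cyp27b1, which makes active vitamin D, was at 85.0 TPM in S1 and 0.9 in S2. Ptgds, a prostaglandin D synthase, was at 423 and 0.6 TPM, Pde1a at 127 and 0.8, and Chrna4 at 63.7 and 0.3. Mir1892 was at 49.2 TPM in S1 and listed at 0 in S2, but this gene spans 80 bases, and TPM of so short an RNA can rest on few reads. In the other direction, Kap was 1137-fold higher in S2 (64255 against 56.5 TPM). Napsa, an aspartic protease of lysosomes, was 833-fold higher (11494 against 13.8 TPM), Akr1c18, a progesterone-metabolising reductase, 745-fold (1192 against 1.6 TPM) and Slc7a12 645-fold. Transporters of organic anions and sugars stood at under 1 TPM in S1. They were Slc22a7 (877 TPM in S2), Slc22a19 (670), Slc22a13 (519.6) and Slc5a10 (493), and the same held for Serpina1f (873) and Cyp2a4 (613).

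In total 1062 genes were at least 2-fold higher in S1 than in S2 and 2840 lower. The 27.2% share of higher genes changed with quantile normalization, which gave 1532 higher and 1720 lower, a share of 47.1%. It moved the median difference of all genes by 0.26, from -0.18 to 0.08. Median-of-ratios scaling left the share at 27.2%, and removing mitochondrially encoded genes, Gpx3 and Kap lowered it to 21.7%. Among genes with a TPM of at least 100 in the higher segment, 230 were higher in S1 and 242 lower. Endothelial markers were also lower in S1 than in S2, with a median of -2.91, as were immune markers, with -2.28.

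S1 against S3 compared the ends of the tubule. Gatm was 4072-fold higher in S1. Spp2, a secreted phosphoprotein, was 1251-fold higher (4627 against 3.7 TPM) and Slc34a1 602-fold. Alpl, tissue-nonspecific alkaline phosphatase, was at 1129 and 0.8 TPM, Ugt2b38 at 616 and 0.1, Fam151a at 518 and 0.1, and Acss1 at 682 and 0.5. In S3, Akr1c18 was 3059-fold higher than in S1 (4895 against 1.6 TPM), Kap 1694-fold, Napsa 1535-fold and Slc7a12 1219-fold. Kcnk1, a two-pore potassium channel, was at 849.7 TPM in S3 and 0.5 in S1. Serpina1f, Slc22a7, Cyp2a4 and Slc22a19 were again under 1 TPM in S1, with 1416, 1155, 938 and 957 TPM in S3. The mitochondrial glutamine tRNA mt-Tq was at 1260 TPM in S3 and listed at 0 in the others. For RNAs this short, TPM can rest on few reads, and the read numbers are not known here. The counts were 1681 genes higher in S1 than in S3 and 2108 lower, and 293 and 333 among genes with a TPM of at least 100 in the higher segment. Endothelial markers were also lower in S1 than in S3, with a median of -1.42, while immune markers differed less than 2-fold, with -0.35 (percentile 14.29).

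S2 against S3 gave fewer differences: 1403 genes were at least 2-fold higher in S2 and 359 lower. Quantile normalization gave 860 and 544, so the share of higher genes went from 79.6% to 61.3% while the median of all genes moved by -0.17. That share was 76.4% under median-of-ratios scaling and 83.7% without mitochondrially encoded genes, Gpx3 and Kap. At a TPM of at least 100 in the higher segment the numbers were 80 and 51. Cyp4a14, a fatty acid hydroxylase, was 210-fold higher in S2 than in S3 (315 against 1.5 TPM), Slc22a6 217-fold, Slc13a3 206-fold, Gatm 187-fold and Slc34a1 131-fold. Slc22a8 (349 TPM in S2), Inmt (202), Car4 (171), which is the membrane-bound carbonic anhydrase, and Alpl (161) were under 1 TPM in S3. In S3, Bcat1, a cytosolic branched-chain aminotransferase, was 57.3-fold higher (120.4 against 2.1 TPM), Frzb, a secreted Wnt antagonist, 12.9-fold (18 against 1.4 TPM) and Igf2 6.83-fold (56.0 against 8.2 TPM). Serpina6 was at 10.1 TPM in S3 and 0.7 in S2. The rest of the 10 were short RNAs: mt-Tq, mt-Tl2, Mir5113, Mir1892 and Snord96a, each listed at 0 in S2, and Mirlet7b (24.9 against 3.3 TPM). Markers of endothelial, immune and stromal cells were also higher in S2 than in S3, as given below.

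The position of S2 between its neighbours was taken over the 3789 genes that differed at least 2-fold between S1 and S3, with S3 at 0 and S1 at 1. The median position was 0.234 (quartiles 0.0736 and 0.445), and 20.8% of the genes lay nearer S1. For the 1681 genes higher in S1 the median was 0.316, and for the 2108 genes higher in S3 it was 0.184. Quantile normalization turned this order, with 0.189 for genes higher in S1 and 0.249 for genes higher in S3. Among genes of at least 100 TPM in the higher of S1 and S3, the medians were 0.298 and 0.193. Across genes, log2 values of S2 correlated more closely with S3 (r = 0.955) than with S1 (r = 0.884). By the title numbers S2 shared animals with S3 but not with S1, and what this adds to the closeness cannot be separated here. S1 and S3 also shared animals and correlated least (r = 0.847). Genes are not independent replicates.

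Glucose and energy metabolism also differed by segment. Of 9 measured genes of gluconeogenesis, 5 were at least 2-fold higher in S1 than in S2 and 7 than in S3, and none was lower. The median difference was 1.20 for S1 minus S2 (percentile 99.99) and 1.21 for S1 minus S3 (percentile 99.9). For S2 minus S3 it was 0.34 (percentile 99.8), with 8 of 9 members higher in S2, 1 of them at least 2-fold. G6pc, glucose-6-phosphatase, was at 1044, 198 and 31.5 TPM in S1, S2 and S3, and Slc37a4, which brings glucose-6-phosphate to it, at 827, 288 and 157. Pck1, the cytosolic PEP carboxykinase, was similar throughout (2105, 2136 and 1638 TPM). The 13 glycolysis genes split. Aldoa, Tpi1, Gapdh and Pfkm were at least 2-fold higher in S1 than in S2, and Hk1, Pfkp and Pkm lower. Pkm, the muscle-type pyruvate kinase, was at 1.9 TPM in S1, 50.1 in S2 and 75.9 in S3. The list's median for S1 minus S2 was 0.69 (percentile 99.93) and its mean -0.12, so they differ in sign. For S1 minus S3 they were 0.57 (percentile 98.89) and -0.24.

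Of 24 nuclear-encoded oxidative phosphorylation genes, 23 were higher in S1 than in S2, 2 of them at least 2-fold (Sdha and Sdhd). The median difference was 0.71 (percentile 100), against 0.06 for matched lists. For S1 minus S3 it was 0.61 (percentile 99.97). The mitochondrially encoded genes went the other way. The 7 protein genes with a value were each lowest in S1 and highest in S2, for example mt-Co1 at 9619, 26268 and 15468 TPM in S1, S2 and S3. Mitochondrial fatty acid oxidation had no common direction (median 0.09 for S1 minus S2, percentile 52.01, and 0.17 for S1 minus S3, percentile 83.05). Within it Acadm, the medium-chain dehydrogenase, was at 276 TPM in S1, 2368 in S2 and 3784 in S3, and Acaa2, a thiolase, at 1138, 187 and 4.0. Of 20 peroxisome genes 7 were at least 2-fold lower in S1 than in S2 and 2 higher (median -0.19, percentile 6.7). Hao2, hydroxyacid oxidase, was at 168, 1785 and 1890 TPM and Ehhadh at 77.7, 666 and 831. Acaa1b peaked in S2 at 453 TPM. For S1 minus S3 the peroxisome median was -0.39 (percentile 5.42), and for S2 minus S3 0.12 (percentile 99.91).

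Transport genes formed opposite gradients. In the sodium, phosphate and bicarbonate list, 7 of 13 genes were at least 2-fold higher in S1 than in S2 and 2 lower, with a median of 1.20 (percentile 100). The median was 4.28 for S1 minus S3 and 1.06 for S2 minus S3 (percentile 100 in both). Slc4a4, the basolateral sodium-bicarbonate cotransporter, was at 686, 115 and 24.0 TPM. Slc9a3, the sodium-proton exchanger NHE3, was at 52.5, 11.4 and 0.1, and Car14 at 402, 117 and 0.4. The water channel Aqp1 was the opposite, with 33, 383 and 561 TPM, and Car4 was highest in S2. Amino acid transporters divided evenly: of 18, 8 were at least 2-fold higher and 7 lower in S1 than in S2 (median 0.04, percentile 54.32, with a mean of -0.22), and 8 higher and 8 lower than in S3 (median -0.40, percentile 4.38). The neutral amino acid transporter Slc6a19 was at 874, 19.2 and 15.7 TPM, and the related Slc6a18 at 5.4, 1133 and 1805. Slc7a7, Slc7a8, Slc3a2 and Slc43a2 went with Slc6a19, and Slc38a3, Slc1a4 and Slc7a12 with Slc6a18.

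Of 23 organic anion and cation transporters, 13 were at least 2-fold lower in S1 than in S2 and 1, Slc22a5, higher, with a median of -1.83 (percentile 0). Against S3, 7 were higher and 9 lower in S1 (median 0.29, percentile 95.92, with a mean of -0.84), and 8 were higher and none lower in S2 (median 0.23, percentile 100). S2 and S3 shared high levels of Slc22a12, the urate transporter (64.8, 687 and 507 TPM in S1, S2 and S3), Slc22a2 (32.5, 279 and 269) and Slco1a6 (12.6, 304 and 422). S1 and S2 shared Slc13a1, the sulfate transporter (291, 156 and 2.4 TPM), Abcc2 (65.6, 49.1 and 3.8) and Slc22a8. Of 18 genes of receptor-mediated endocytosis, 4 were at least 2-fold higher in S1 than in S2 and none lower (median 0.57, percentile 99.87). They were Ctsb, Dab2, Ctsl and Ctns. The receptors Lrp2 (143, 228 and 259 TPM) and Cubn (46.0, 61.8 and 59.7) differed less than 2-fold.

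**Figure D2:**
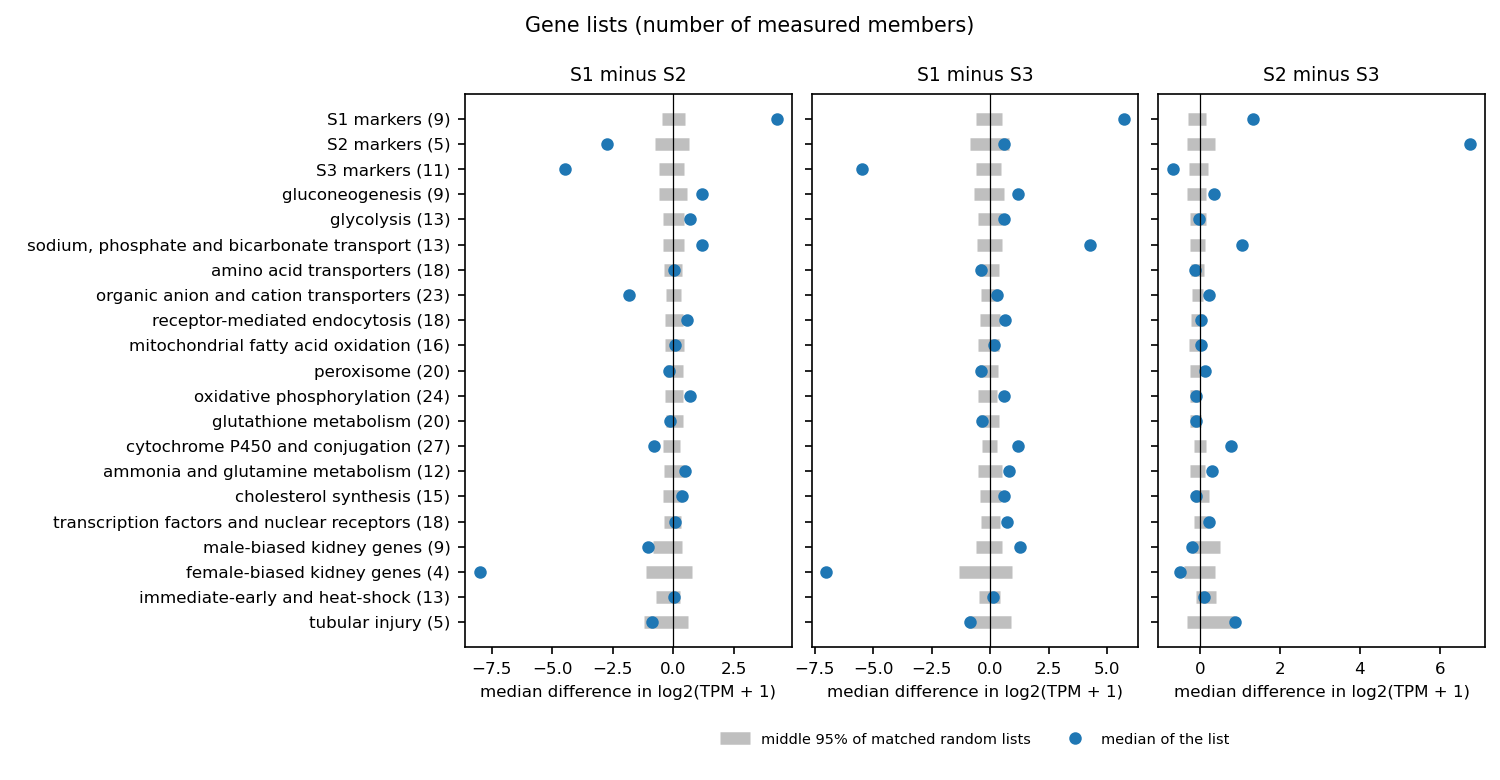
Median difference in log2(TPM + 1) of each gene list for S1 minus S2, S1 minus S3 and S2 minus S3, with the number of measured members in parentheses. Blue points are list medians and grey bars hold the middle 95% of 10000 random lists matched on expression. Sodium, phosphate and bicarbonate transport lies at 4.28 for S1 minus S3 and organic ion transporters at -1.83 for S1 minus S2.

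Detoxification genes were split by segment. In the list of cytochromes P450 and conjugation, 8 of 27 genes were at least 2-fold higher and 11 lower in S1 than in S2 (median -0.81, percentile 0.01). Against S3, 14 were higher and 7 lower in S1 (median 1.20, percentile 100), and 13 were higher and 2 lower in S2 (median 0.79, percentile 100). Peaks in S2 were found for Cyp4a14 (1.0, 315 and 1.5 TPM in S1, S2 and S3), Cyp2e1 (2.6, 93.7 and 0.2) and Ugt1a2 (340, 954 and 26.9). Cyp24a1, which breaks down active vitamin D, was at 58.5, 4.0 and 0.1 TPM. Of 20 glutathione genes, 8 were at least 2-fold higher and 7 lower in S1 than in S3 (median -0.37, percentile 6.17, with a mean of 0.49). The peroxidases Gpx3 (114421, 12746 and 3489 TPM) and Gpx1 (6258, 3617 and 819) were highest in S1. The synthesis and turnover genes Gclc (37.3, 199 and 490), Gss (234, 565 and 961) and Ggt1 (75.1, 1305 and 1539) were highest in S3.

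In ammonia and glutamine metabolism 6 of 12 genes were at least 2-fold higher and 3 lower in S1 than in S3 (median 0.81, percentile 99.87). Prodh2 was at 359, 93.9 and 0.2 TPM. The glutamine transporter Slc38a3 was at 0.3 TPM in S1 and 98.7 in S3. For S1 minus S2 this list's median was 0.47 (percentile 98.25) and its mean -0.03. Of 15 cholesterol synthesis genes, 6 were at least 2-fold higher and 3 lower in S1 than in S3. The median was 0.61 (percentile 99.53) and the mean -0.06. Among the lower genes were Sqle (13.6, 50.6 and 102 TPM) and Cyp51 (15.6, 271 and 348). For S1 minus S2 the median was 0.37 (percentile 97.8) and the mean -0.14.

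Among 18 transcription factors and nuclear receptors, 7 were at least 2-fold higher and 4 lower in S1 than in S3 (median 0.72, percentile 100). Ppargc1a, a coactivator of mitochondrial genes, was at 53.7, 14.2 and 3.7 TPM, and Maf at 19.1, 7.7 and 2.0. Ppara was at 96.7, 37.5 and 21.8 TPM and Nr1h4, the bile acid receptor, at 118, 45.4 and 29.4. Hnf4a, a proximal tubule regulator, differed little (112, 117 and 136 TPM). The estrogen receptor gene Esr1 was lowest in S1 (0.3, 5.2 and 7.4 TPM). The 4 genes listed as female-biased in kidney were at least 2-fold lower in S1 than in S2 (median -7.99, percentile 0). Prlr, the prolactin receptor, was at 19.1, 414 and 532 TPM. Of the 9 measured genes listed as male-biased, 3 were higher and 5 lower in S1 than in S2 (median -1.03, percentile 0.58). Against S3 their median was 1.26 (percentile 100) and their mean was negative. Slc7a13 was listed at 0 in S1 and was at 1.1 TPM in S2 and 2.9 in S3, and Slco1a1 was listed at 0 in each.

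Markers of other cells were unevenly spread. The 7 endothelial markers were at least 2-fold higher in S2 than in S1 and in S3, with medians of -2.91 for S1 minus S2 and 1.38 for S2 minus S3. Each was also lower in S1 than in S3, 4 of them at least 2-fold (median -1.42, percentile 0.18). Plvap was at 29.6, 275 and 136 TPM and Emcn at 14.1, 156 and 51.3. The 8 macrophage and immune markers were also at least 2-fold higher in S2 than in both others (medians -2.28 and 2.21), and differed less than 2-fold between S1 and S3. Cd74 was at 50.1, 193 and 37.8 TPM and C1qb at 2.2, 23.3 and 3.5. Of 5 stromal and mural markers, 4 were at least 2-fold higher in S2 than in both others, at no more than 5.1 TPM, and Rgs5 was not. Among matched lists the endothelial and immune medians stood at percentile 0 for S1 minus S2 and the stromal one at 0.04, and each of the 3 stood at 100 for S2 minus S3. In the thick ascending limb list, Umod was at 0.2, 21.1 and 29.1 TPM and Egf at 3.3, 19 and 18.5 (median of 3 genes -2.22 for S1 minus S2, percentile 0.29). The other measured gene, Slc12a1, differed by just 0.11 for S1 minus S2, and Cldn16 and Kcnj1 were at no more than 0.1 TPM. Of 12 genes listed for principal and intercalated cells of the collecting duct, 3 reached 1 TPM, and these were highest in S1, with Aqp3 at 28.3, 5.2 and 0.1 TPM, Fxyd4 at 32.3, 7.4 and 0.9 and Slc26a4 at 1.2, 0.1 and 0.1. Of the thin limb list, 2 genes were measured and both were at least 2-fold higher in S1 than in the others, among them Epha7 at 2.5, 0.5 and 0.2 TPM. Both measured genes of the podocyte list were highest in S2, Podxl at 1.4, 13.4 and 3.1 TPM and Synpo at 0.7, 2.3 and 1.2. The distal tubule gene S100g was at 58.2, 59.9 and 6.8 TPM. No red blood cell gene reached 1 TPM.

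**Figure D3:**
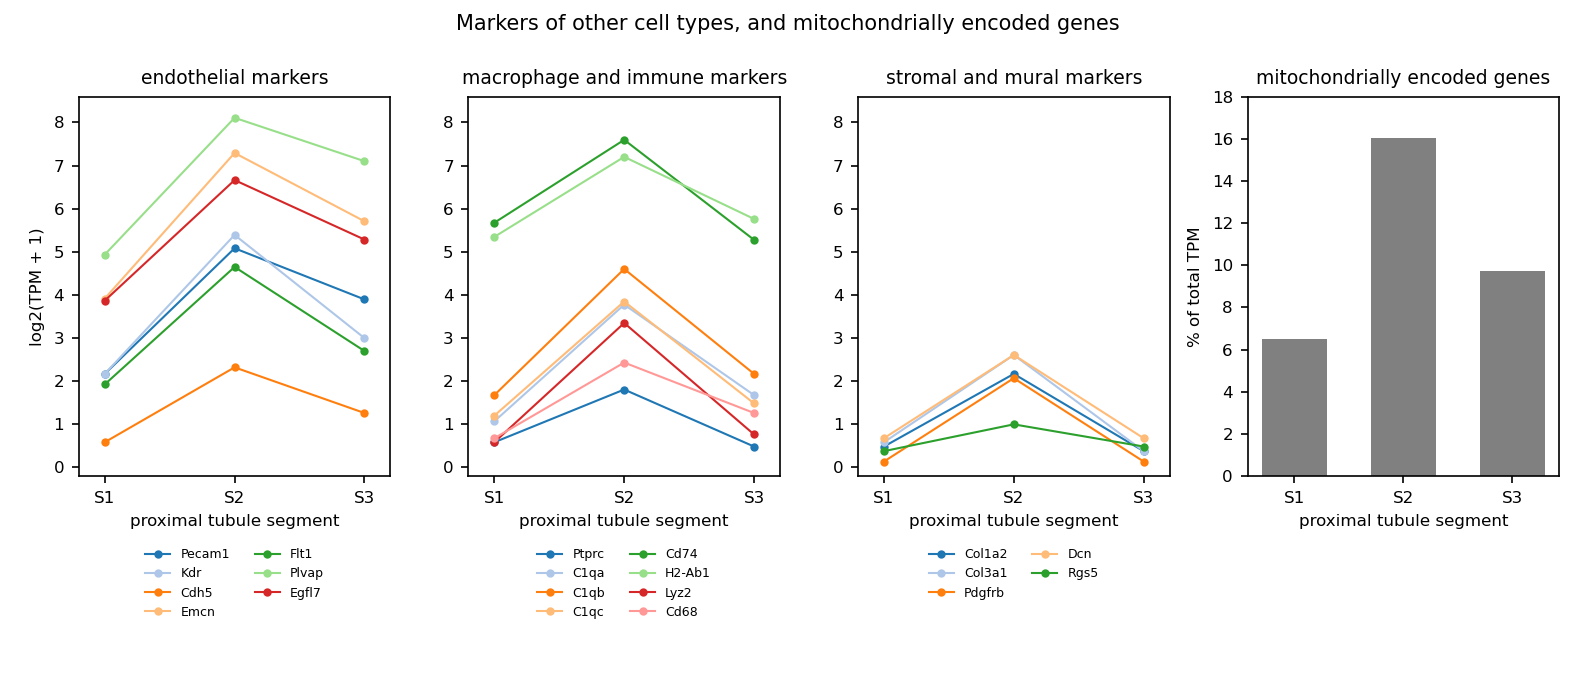
Left panels give log2(TPM + 1) of endothelial, macrophage and immune, and stromal and mural markers by segment, 1 line per gene and 1 value per point. The right panel gives the share of the TPM total in mitochondrially encoded genes as bars from 0, at 6.50% in S1, 16% in S2 and 9.72% in S3. Plvap peaks in S2 at 275 TPM, as does Cd74 at 193.

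Genes of early stress differed little as a list. Of 13 measured immediate-early and heat-shock genes, 2 were at least 2-fold higher and 3 lower in S1 than in S2 (median 0.04, percentile 78.6), and Fos was at 0.7 TPM in each segment. Among 5 tubular injury genes, Havcr1 (KIM-1) was listed at 0 in S1 and was at 0.8 TPM in S2 and 4.4 in S3. Clu was at 0.8, 25.3 and 78.5 TPM, and Spp1, osteopontin, at 4790, 903 and 140. The list's median was -0.87 for S1 minus S2 (percentile 9.63), -0.86 for S1 minus S3 (percentile 3.29) and 0.87 for S2 minus S3 (percentile 97.7). As to the sex given in the labels, Xist was at 11.7, 27.9 and 16.5 TPM, and the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0.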

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

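The alternatives that removed mitochondrially encoded genes, Gpx3 and Kap, or kept protein-coding genes alone, were chosen after the data were seen. So were pseudocount 5, the scalings and the filters for the position of S2, and pseudocount 5, median-of-ratios scaling and the filters for list medians. No paired analysis was possible because each segment has 1 value, with no number that ties it to an animal. For the same reason the planned block terms, fits to single libraries, moderation settings, adjusted p with a fold threshold, left-out samples and gene set tests were not run, nor was the position of S2 over all genes past a test. The depth is unknown, so what it limits could not be computed. No position, called list median or called gene difference changed sign under the alternatives run. Of list medians 553 values moved by at most 0.58 on the log2 scale and 41 by more, and of gene differences 7396 and 407. Of counts and positions 71 values stayed within 1.5 times that reported and 33 did not. The median position of S2 over all genes ranged from 0.194 to 0.241. Leaving out the filter left the counts as they were, because a 2-fold difference at pseudocount 1 needs a TPM of at least 1.

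With pseudocount 0.1, which widens differences of low genes, 4738 genes were lower in S1 than in S2, 3201 lower in S1 than in S3, 3129 higher in S2 than in S3 and 544 lower. Of all genes 2063 were above both other segments in S2, more than the 1215 in S1, and the position for genes higher in S3 was 0.0861. With pseudocount 5, which shrinks them, 575 genes were higher and 994 lower in S1 than in S2, 879 higher and 1040 lower in S1 than in S3, and 350 higher and 105 lower in S2 than in S3. Then 2254 genes differed among segments, and 545, 146 and 97 were above both others in S1, S2 and S3. With a filter of TPM 5, which compares fewer genes, 1504 were lower in S1 than in S2, and 698 were higher and 183 lower in S2 than in S3. In all 3086 differed, with 317 above both others in S2 and 163 in S3. Quantile normalization gave 1720 genes lower in S1 than in S2, 860 higher and 544 lower in S2 than in S3, 413 above both others in S2, and a position of 0.189 for genes higher in S1, below the 0.249 for genes higher in S3. The cause was not tested. Without mitochondrially encoded genes, Gpx3 and Kap, 886 genes were above both others in S1 and 1060 in S2, the reverse of the reported order. With protein-coding genes alone, which are fewer, 637 were higher in S1 than in S2 and 124 lower in S2 than in S3. Then 611, 554 and 113 were above both others in S1, S2 and S3, and the position for genes higher in S3 was 0.112, for which the cause was not tested.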

Other observations

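Some gene families also differed by segment. They were chosen after their values were seen, and a few members (4 UDP-glucuronosyltransferases, H2-Ab1 and Zfp36) are in the fixed lists too. The 4 Iroquois transcription factors measured were each at least 2-fold lower in S1 than in S2 and S3, with medians of -2.64 and -3.74 (percentiles 0.1 and 0). Irx3 was at 0.3, 22.7 and 20.6 TPM in S1, S2 and S3, and Irx2 at 0.1, 8.7 and 31. The 3 thick ascending limb markers measured had medians of -2.22 and -2.18 in the same contrasts. Slc12a1 among them differed less, by 0.11 and -0.51. Of 10 claudins, which form tight junctions, 6 were at least 2-fold lower in S1 than in S2 and none higher (median -1.41), beside medians of -2.91 for endothelial and -2.22 for thick ascending limb markers. Cldn7 was at 2.2, 36.5 and 89.3 TPM, and Cldn3 was listed at 0 in S1, with 50.2 and 104.5 in the others. The 7 clade A serine protease inhibitors were at least 2-fold lower in S1 than in S3 (median -3.02). Of 12 UDP-glucuronosyltransferases 9 were at least 2-fold higher and 2 lower in S1 than in S3 (median 2.18). Among the 9, Ugt1a6b, Ugt2b37 and Ugt2a3 were low even in S1 (1.3, 1.6 and 2.1 TPM), and members may share reads.

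Of 18 genes with symbols of the vacuolar ATPase (1 a pseudogene), whose subunits acidify endosomes and lysosomes, 5 were at least 2-fold higher in S1 than in S2 and 6 than in S3, and none was lower (medians 0.88 and 0.65). Cytosolic ribosomal protein genes went slightly the other way: 68 of 82 were lower in S1 than in S2, with a median of -0.34 against 0.09 for matched lists. Of 21 genes with major histocompatibility symbols (H2-T-ps, a pseudogene, among them) 11 were at least 2-fold lower in S1 than in S2 and 2 higher (median -1.27). The 8 macrophage and immune markers, of which H2-Ab1 is one, were also at least 2-fold lower in S1 (median -2.28). For S1 minus S2 the median of 81 genes with mitochondrial ribosomal protein symbols (3 of them pseudogenes) was 0.26, against 0.063 for matched lists. That of 40 genes with proteasome symbols (among them 2 pseudogenes and Psmc3ip, which is no subunit) was 0.08 (percentile 64.4). That of 314 Zfp genes was 0, at percentile 100 because matched lists had a median of -0.24. That of 27 Hox entries, with Hoxd4 entered more than once, was -0.54 (percentile 11.8), within the range of matched lists. The Hox medians lay below that range in the other contrasts. They were -0.55 for S1 minus S3 (percentile 0.135) and -0.15 for S2 minus S3 (percentile 0.03). Each family median was also taken under 6 alternatives. For S1 minus S2 the proteasome median changed sign under 2, the highest Hox value was 0 and the Zfp values went from -0.15 to 0.36. The other family medians given here kept their sign.

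All tests in the rest of this part were chosen after the values were seen, and a difference between the segments themselves stayed open and untested in each. The first pattern is that, among the 3789 genes that differed at least 2-fold between S1 and S3, values in S2 mostly lay between the others (quartiles of position 0.0736 and 0.445). A mixture of the S1 and S3 columns could not give the 28 genes of at least 100 TPM that were at least 2-fold higher in S2 than in both. Examples are Hpd (0.9, 294.7 and 8.0 TPM) and Nat8 (6.8, 200 and 2.9). Of the 28, 5 are in the fixed lists of other cells and more, such as Ly6c1 (38.3, 332.6 and 130.9 TPM), are known from them. S1 tubule in the S2 samples would give its genes a common ratio, but 35.9% of 103 genes with at least 50 TPM in S1 and 20 times that of S3 lay below 0.5 times the median S2-to-S1 ratio of 0.142. For 134 genes chosen likewise for S3 over S1 that share was 8.21%, around a median S2-to-S3 ratio of 0.552, but 7 had ratios above 1, led by Tmigd1 (292.1 and 114 TPM in S2 and S3), and Bcat1 (2.1 and 120.4) leaves room for little S3 tubule. The spread between animals is unknown, and by the title numbers S1 and S2 shared none. What is said above of a mixture and of S1 tubule therefore holds for these columns alone. S3 tubule as the source of the genes high in S3 was left undecided.

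Next, 19 of 20 endothelial, stromal and immune markers were at least 2-fold higher in S2 than in both other segments. A general rise of low transcripts in S2 is argued against by the smallest excess of the 3 list medians over matched lists, 1.37 against S3. If a lower share of proximal tubule cells raised all other types alike, markers of other nephron parts and podocytes would rise too. The 12 measured had a median of -0.033 for S2 minus S1 (quartiles -1.31 and 1.27), against 2.34 for the 20 (quartiles 1.83 and 2.83). They went both ways, with Podxl, Synpo, Umod and Egf higher in S2 and Aqp3 and Fxyd4 higher in S1. Some, such as Aqp3, Fxyd4 and S100g, were already well above 1 TPM in S1, so they cannot show a small share of such cells. Other cell types need not rise alike either, so this explanation was left undecided. Endothelial, stromal and immune cells taken along with the S2 tubules remained a candidate source, with Plvap at 275 TPM and Cd74 at 193 as their most abundant markers.

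Last, nuclear-encoded oxidative phosphorylation genes were higher in S1 than in S2 while mitochondrially encoded ones were lower. The share of the TPM total taken by mitochondrially encoded genes, Gpx3 and Kap is argued against for the nuclear part, since its median stayed at 0.60 without them. Loss of cytosolic mRNA from S2 would lower ribosomal protein genes too, but their median for S1 minus S2 was -0.34. For the mitochondrially encoded part such loss was left undecided: the nuclear RNAs Malat1, Neat1 and Xist were also higher in S2 than in S1, with a smallest ratio of 1.93. However, the higher mitochondrial share alone would set every other gene 0.15 higher in S1, and ribosomal protein genes went the other way.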
